A study of Mus with 2 samples.

How the data were processed

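Bone marrow from the hindlimbs of mice in 2 groups, named ground and running, was profiled by single-cell RNA sequencing, with 1 library per group. The libraries were made with a droplet-based 3′ gene expression kit (Chromium, v3 chemistry), per the labels' protocols. This kit reads the 3′ end of each transcript and tags every captured molecule with a unique molecular identifier (UMI), so that copies made by PCR are counted once. The labels do not say how many mice went into each library, how long or on what device the mice ran, or what ground means beyond its contrast with running.

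The deposited files hold raw UMI counts per gene and cell barcode, written by Cell Ranger 5.0.0, per the file headers. STAR and the mouse build mm10 are named in the submitters' processing notes. The lowest total of any barcode was 501 UMIs in the ground matrix and 500 in the running matrix, so both matrices appear to have been limited to barcodes with about 500 UMIs or more. Any further filter applied upstream is not given in the sources used here. Gene symbols and Ensembl identifiers were taken from the files, and gene coordinates from RefSeq annotation of assembly GRCm38.p6, which is the assembly behind mm10.

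Barcodes were kept with at least 500 UMIs, at least 250 detected genes and at most 10% mitochondrial UMIs. This removed 253 barcodes (2.76%) from ground and 293 (3.09%) from running. Doublets were called in each library with Scrublet, as implemented in scanpy 1.11.5, with the score threshold set by the tool, and were removed. The threshold was 0.242 in ground and 0.322 in running, and 243 barcodes (2.73%) and 100 barcodes (1.09%) were called. Counts were then scaled to 10000 per cell and log-transformed, 2000 variable genes were selected with the library as batch key, and both libraries were clustered jointly (30 principal components, 15 neighbours, Leiden algorithm in igraph 0.11.9, resolution 1). No batch integration was applied. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used.

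The 31 clusters were named from marker genes of 22 cell types. The 10 leading genes of a cluster were those with the highest fold over the mean of the other clusters (10 CPM added to both) among genes seen in at least 25% of its cells. A cluster took the name of the type with most markers among these genes and needed at least 3 detected markers. All clusters received a name, giving 16 classes, which are called by name with the ending "like". Cluster 18, a small monocyte-like cluster, was led in part by the stress genes Hspa1a, Hspa1b and Nr4a1. Clusters 10 (monocyte-like), 21 (erythroid-like) and 22 (macrophage-like) had median UMI counts below the library median divided by 3 and kept their names because markers of the type were among their leading genes. Cluster 30 (B cell-like, 7 ground and 37 running cells) also carried abundant neutrophil transcripts.

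Expression was compared between the libraries as CPM, which scales raw counts to the total UMIs, from counts summed over all cells or over the cells of a class. Classes were compared if they held at least 200 cells in each library, and macrophage-like cells if they held at least 50. Sums of counts carry exact Poisson intervals, shares of cells carry exact binomial (Clopper-Pearson) intervals, and ratios of CPM carry exact conditional binomial intervals, all at 95%. Ratios of shares carry 95% intervals from a normal approximation on the log scale. These intervals cover counting error only. With 1 library per group there was no replicate check of any difference, and no test, p-value or count of changed genes was computed from cells.

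Each of 31 gene lists was summarised by the median log2 ratio (running over ground) of the members with at least 50 UMIs in the class. The percentile of that median among 10000 random gene lists of the same size, matched on mean expression, is given as a description of these libraries. The text names the 10 highest and 10 lowest ratios among genes with at least 200 UMIs over all cells, and the 3 highest and 3 lowest in each class. Mitochondrial, ribosomal protein, haemoglobin, antigen receptor, unnamed, Xist and Y-linked genes were left out of both rankings. Markers of other classes, and granule genes outside neutrophil and progenitor classes, were left out of the class rankings because they can be free RNA. It also names Rcn2, Nrp2 and Itgb1, and from each list described 2 to 4 members with the largest ratio in size among those with at least 100 UMIs. The markers, gene lists, filters, named-gene rule and most alternatives were fixed before the data were examined.

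The interval and list procedures were tested on simulated counts for the monocyte-like comparison of running with ground. Of 10518 genes, 196 were given a 2-fold difference. The intervals covered the simulated ratio for 95.6% of genes, and 98.0% of the changed genes were recovered. Of 100 unchanged lists, 5 lay outside the central 95% of random lists, and 100 of 100 lists with a difference lay above percentile 97.5. The counts were Poisson draws from a single pooled profile and the lists were drawn at random, so variation between cells or mice was not simulated. The test therefore checks the calculation only, not how the intervals or percentiles hold in real cells.

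The alternatives tried were a minimum of 1000 UMIs per cell, at most 5% mitochondrial UMIs, doublets kept, Leiden resolutions 0.5 and 2, and other denominators for shares. For expression they were ratios centred on the median gene, totals without haemoglobin, immunoglobulin and granule genes, a mean of CPM over cells, the class proportions of ground in both libraries, list members with at least 200 UMIs, and cells thinned to 1000 UMIs. Chosen only after the data had been seen were the class proportions of ground for list medians, a single Scrublet threshold for both libraries, B cell-like cells without cluster 30, and mature neutrophil-like cells of cluster 17 alone. No reads were realigned, and genes of near-identical copies, such as H2-Q6 and H2-Q7, are reported as uncertain because the counting could divide their reads between them.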

Results

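Bone marrow cells of mice kept in a ground group or in a running group were compared by single-cell RNA sequencing. Each group had 1 library, and the labels do not say how many mice it held. The ground library held 9162 barcodes with 85014860 UMIs in all and a median of 5814.5 UMIs per barcode. The running library held 9473 barcodes with 79990530 UMIs and a median of 5039 UMIs. After filtering and removal of doublets, 8666 ground cells and 9080 running cells remained, with medians of 5938 and 5146 UMIs and of 1639 and 1536 genes per cell. Mitochondrial transcripts made up a median of 1.16% of the UMIs of a ground cell and 1.05% of a running cell. Haemoglobin transcripts took 1.08% of all UMIs in ground and 0.784% in running, and granule protein transcripts 19.4% and 16.6%. Both libraries were of male type, since the Y-linked gene Ddx3y stood at 56.9 CPM in ground and 61.3 CPM in running, whereas the female-specific transcript Xist had 4 and 9 UMIs. No difference given here has a replicate check, and all intervals cover counting error only. With 1 library per group, a difference in handling or library preparation cannot be told apart from a difference between the groups.

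The first question was whether the cellular makeup of the marrow differed between ground and running. Macrophage-like cells, led by the complement genes C1qa, C1qb and C1qc and by the haem oxygenase gene Hmox1, made up 0.727% of ground cells (63 cells, 95% interval 0.559 to 0.929%) and 2.42% of running cells (220 cells, 2.12 to 2.76%). Their share was 3.33 times as high in running (2.52 to 4.40). Mesenchymal stromal-like cells, which express the niche chemokine Cxcl12, were also more frequent, at 0.265% (23 cells) and 0.551% (50 cells), a ratio of 2.07 (1.27 to 3.40). Granulocyte-monocyte progenitor-like cells, marked by the azurophil granule genes Elane, Mpo and Prtn3, were less frequent in running, at 4.30% against 2.68% (ratio 0.622, 0.530 to 0.729). The macrophage-like cells were shallow, with medians of 823 and 977 UMIs, close to the 500 UMI minimum of the matrices, and that minimum can set their share.

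Along the neutrophil series the running library was shifted towards mature cells. Immature neutrophil-like cells, which hold specific granule transcripts such as Ltf and Camp, stood at 15.1% in ground and 12.6% in running (ratio 0.831, 0.772 to 0.894). Mature neutrophil-like cells stood at 36.1% and 40.1% (ratio 1.11, 1.07 to 1.15). Within the series alone, mature cells made up 65.0% in ground and 72.5% in running, and progenitor-like cells 7.75% and 4.84%. Monocyte-like cells were less frequent in running (14.7% and 12.4%, ratio 0.843, 0.783 to 0.908), as were erythroid-like cells (6.31% and 5.22%, ratio 0.827, 0.734 to 0.932). The low-UMI cluster 10 held 17.4% of the monocyte-like cells in ground (223 cells) and 9.21% in running (104 cells). Part of the lower monocyte-like share therefore lies in this shallow cluster. Among cells with at least 1000 UMIs the monocyte-like ratio was 0.874, and the ratio without cluster 10 was not computed.

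T cell-like cells were more frequent in running, at 2.39% in ground and 3.17% in running (ratio 1.33, 1.11 to 1.58). Among lymphoid cells alone their share was 13% and 15.9%, while B cell-like cells made up 41.4% and 36.6%. Of all cells, B cell-like cells were at 7.62% and 7.32% and B-cell precursor-like cells at 5.56% and 6.23%, with the interval of each ratio including 1. Basophil or mast cell-like cells (1.21% in both libraries), conventional dendritic cell-like cells (1.66% and 1.70%), plasmacytoid dendritic cell-like cells (1.86% and 2.17%), NK cell-like cells (0.646% and 0.837%), plasma cell-like cells (0.323% and 0.264%) and stem and multipotent progenitor-like cells (1.13% and 1.15%) also had ratios whose intervals included 1. All myeloid cells together made up 73.9% of ground and 73.1% of running cells, and all lymphoid cells 18.4% and 20%.

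**Figure D1:**
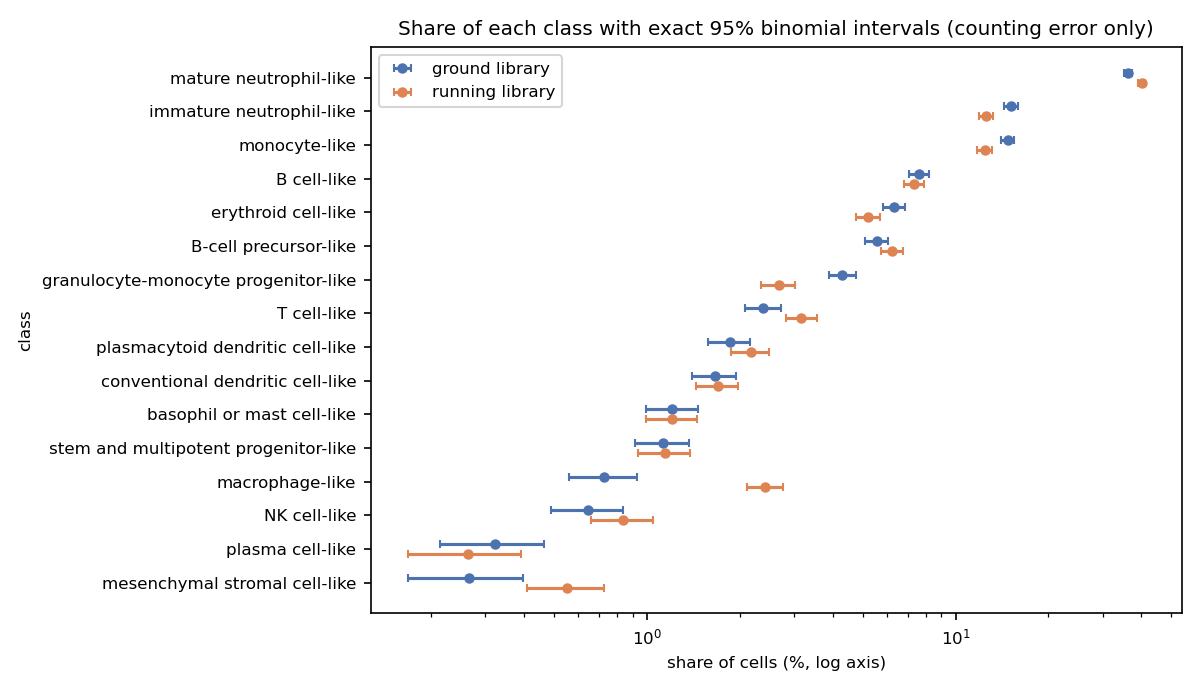
Share of cells (%, log axis) in each class for the ground and running libraries; points are the shares and bars the exact 95% binomial intervals, which cover counting error only. Macrophage-like cells lie at 0.727% in ground and 2.42% in running, the widest gap on the plot.

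Summed over all cells, the genes highest in running included several that mark tissue macrophages. Cd5l, a protein secreted by macrophages, had a log2 ratio of 3.62 (40 and 468 UMIs), Spic, a transcription factor of iron-recycling macrophages, 2.67, and the lectin gene Fcna 2.35. The growth factor gene Igf1 stood at 2.31 and the chemokine receptor gene Ccr3, an eosinophil marker, at 2.35. Macrophage-like cells held most of the UMIs of these 5 genes in running, from 69.0% for Igf1 to 87.8% for Cd5l, and Cd5l, Spic and Fcna are also among the genes that define the class. With the class proportions of ground given to both libraries, the log2 ratios were 1.88 for Cd5l, 1.22 for Spic, 1.05 for Ccr3, 0.80 for Igf1, 0.69 for Fcna and 1.45 for Ifng. Lpl, which encodes lipoprotein lipase, stood at a log2 ratio of 2.54 (2.41 to 2.67), and monocyte-like cells held 366 of its 574 UMIs in ground and 1611 of 3188 in running. The remaining genes of the highest 10 were the platelet chemokine gene Ppbp (3.95), the eosinophil peroxidase gene Epx (2.91), the interferon-induced GTPase gene Gbp6 (2.26) and Ifng, which encodes interferon-γ (2.24). Single running cells supplied 262 of the 369 UMIs of Ppbp, 95 of the 216 of Epx and 66 of the 203 of Ifng.

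Most of the genes lowest in running over all cells were expressed chiefly by neutrophils. They were Igfbp6, which encodes a binding protein of insulin-like growth factors (log2 ratio −3.18), the endothelial lipase gene Lipg (−3.13), Prok2, which encodes a chemokine-like peptide (−2.79), the acute-phase gene Saa3 (−2.74), Ifitm1 (−2.06), the metalloreductase gene Steap4 (−1.92), Wfdc17 (−1.89), the glutathione-cleaving enzyme gene Ggt1 (−1.87), the secretory kinase gene Fam20c (−1.86) and the kinase gene Camkk1 (−1.82). Mature neutrophil-like cells held 84.0% of the Igfbp6 UMIs in ground, and monocyte-like cells 93.2% of those of Saa3, with 161 UMIs in a single cell. Igfbp6, Ifitm1, Steap4, Prok2 and Wfdc17 were also leading genes of mature neutrophil-like clusters 2 or 9, which were mostly of the ground library. Among the gene lists, niche factors had a median log2 ratio of 0.72 over 9 members (Adipoq 1.57, Cxcl12 1.25, Vcam1 1.24), all above 0, but of −0.16 with the class proportions of ground. The azurophil granule list had a median of −0.32, with 10 of 10 members lower (Prtn3 −0.73, Ctsg −0.60), or −0.12 with the class proportions of ground.

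The study is known to follow Rcn2, which encodes the calcium-binding protein reticulocalbin-2, in macrophages. Rcn2 (ENSMUSG00000032320; mm10 chromosome 9, 56041845 to 56059083) had 255 UMIs in ground and 969 in running over all cells, or 3.11 and 12.4 CPM, a log2 ratio of 1.99 (1.79 to 2.20). It was higher in running in each of the 8 classes compared other than macrophage-like cells. The log2 ratio was 2.56 (1.74 to 3.49) in erythroid-like cells, 2.55 in B-cell precursor-like cells, 2.33 in progenitor-like cells, 1.85 (1.49 to 2.22) in monocyte-like cells, 1.73 in mature neutrophil-like cells, 1.58 in B cell-like cells, 1.22 in T cell-like cells and 1.18 (0.42 to 1.97) in immature neutrophil-like cells. In mature neutrophil-like cells of cluster 17 alone, the cluster shared by both libraries, it was 0.69. In macrophage-like cells only 1 and 4 UMIs were counted (log2 ratio −0.20, −3.53 to 5.42), so a difference there was not detectable at this depth.

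Nrp2 (ENSMUSG00000025969; chromosome 1, 62703317 to 62818692) and Itgb1 (ENSMUSG00000025809; chromosome 8, 128685654 to 128733579) encode neuropilin-2 and integrin β1, the reported receptor pair of reticulocalbin-2. Over all cells Nrp2 had a log2 ratio of −0.03 (−0.28 to 0.21) and Itgb1 of 0.13 (0.08 to 0.18). Within classes, the intervals excluding 0 were those of Itgb1 in T cell-like cells, at 0.86 (0.63 to 1.10), immature neutrophil-like cells, at 0.23 (0.06 to 0.40), and erythroid-like cells, at −0.19 (−0.29 to −0.09), and of Nrp2 in monocyte-like cells, at −0.39 (−0.73 to −0.05), and mature neutrophil-like cells, at −1.45 (−3.08 to −0.04, from 17 and 6 UMIs). The list of these 3 genes had a median of 0.13 over all cells, at percentile 63.6, or 0.03 with the class proportions of ground.

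The share of monocyte-like cells with an Rcn2 UMI was 5.95% in ground and 18.5% in running, at medians of 10220 and 9392 UMIs per cell. T cell-like cells, taken as a comparison, showed 4.35% and 11.1% (4491 and 5762 UMIs), B cell-like cells 1.82% and 6.02% (3192 and 3493 UMIs), and macrophage-like cells 1.59% (1 of 63) and 1.82% (4 of 220). After each cell was thinned to 1000 UMIs, the shares in monocyte-like cells were 0.693% and 1.88%, with 123 and 66 shallower cells left out. The thinned shares in T cell-like cells were 0.488% and 2.79%, with 2 and 1 cells left out, and in B cell-like cells 0.464% and 1.97%, with 13 and 6 left out. Thinned macrophage-like cells gave 0 of 23 in ground, which allows a share of up to 14.8%, and 0.980% in running, with 40 and 118 cells left out. These thinned levels rest on few UMIs, and the shares do not set monocyte-like cells apart from lymphoid cells.

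**Figure D2:**
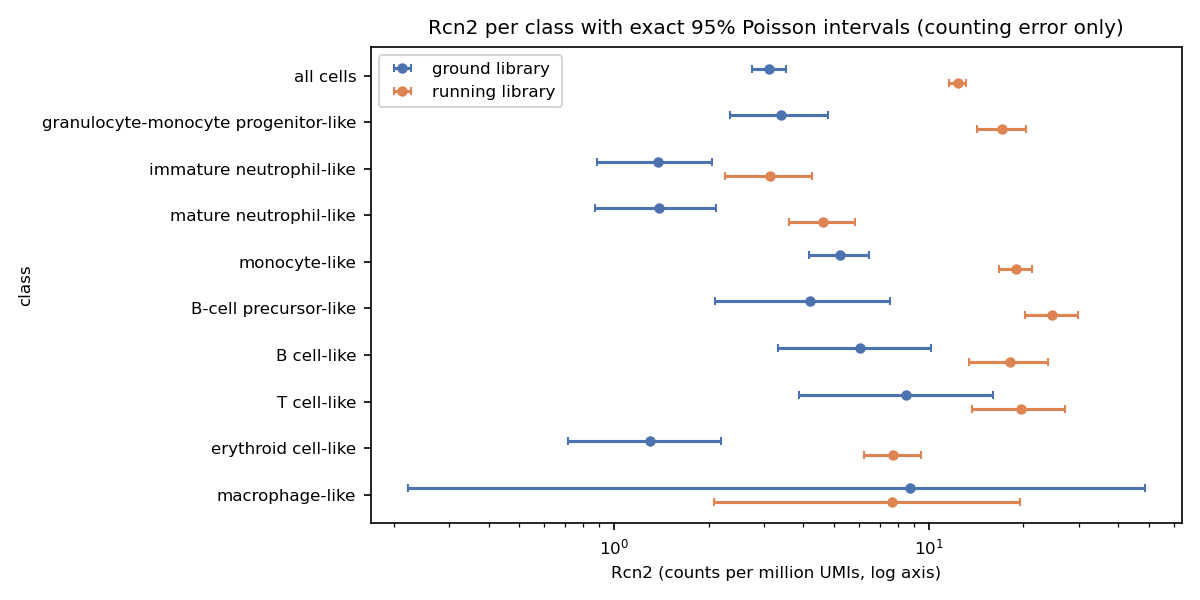
Rcn2 in CPM (log axis) for all cells and for each class in the ground and running libraries; points are values and bars exact 95% Poisson intervals, which cover counting error only. The running value lies above the ground value in all cells (3.11 and 12.4 CPM) and in 8 classes, while the intervals overlap for T cell-like and macrophage-like cells.

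Genes of the type I interferon response, the antiviral programme switched on by interferon receptors, were higher in running in most classes. Their median log2 ratio was 1.24 in progenitor-like cells, 1.09 in monocyte-like cells, 0.98 in immature neutrophil-like cells, 0.89 in erythroid-like cells, 0.80 in mature neutrophil-like cells, 0.74 in T cell-like cells and 0.67 in B cell-like cells. Each of these medians lay above those of all 10000 random lists. Without cluster 30 the B cell-like median was 0.51, and within B cell-like clusters 1 and 16 it was 0.16 and 0.47. In monocyte-like cells 22 of 22 members were above 0, among them the antiviral genes Ifit3 (2.44, 1.96 to 2.95), Ifit2 (1.76) and Oasl2 (1.46). In progenitor-like cells Isg15, a ubiquitin-like modifier, stood at 2.10 and Ifi211 at 1.74, and the median was 0.49 over members with at least 200 UMIs. Ifi27l2a, at 1.55 there, stood at 0.04 as a mean of CPM over cells. B-cell precursor-like cells had a median of 0.16 at percentile 97.8, with Ifi27l2a at 0.66 and Stat2 at −0.50. Over all cells the median was 0.92, and in macrophage-like cells it was 0.82 over 8 members. The neutrophil genes S100a8 and S100a9 rose by about as much in the macrophage-like class, with log2 ratios of 0.79 and 0.86, at 38270 and 34510 CPM in ground and 66380 and 62610 CPM in running.

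Genes of MHC class I presentation, which display peptides to CD8 T cells, were also higher in running in most classes, but the order of the classes differed. Their median was 1.06 in erythroid-like, 0.93 in mature neutrophil-like, 0.72 in immature neutrophil-like, 0.54 in monocyte-like, 0.48 in progenitor-like and 0.31 in B cell-like cells, each above all 10000 random lists. It was 0.17 (percentile 96.4) in T cell-like and −0.01 (percentile 59.7) in B-cell precursor-like cells. The class I genes H2-Q6 (chromosome 17, 35424850 to 35430055) and H2-Q7 (chromosome 17, 35439140 to 35443773) had the largest ratios, 5.27 and 5.07 in mature neutrophil-like cells, 3.80 and 3.79 in immature neutrophil-like cells, and 2.76 and 2.97 in erythroid-like cells. They are near-identical copies, so their separate counts are uncertain, and a variant of these genes between the mice of the 2 libraries was not examined. As a mean of CPM over cells, H2-Q6 stood at 0.57 and H2-Q7 at 2.14 in erythroid-like cells, and H2-Q6 at 1.34 in progenitor-like cells (1.99 from summed counts). H2-K1, a classical class I gene, stood at 1.99 in mature neutrophil-like and 1.44 in immature neutrophil-like cells. MHC class II genes, which present peptides to CD4 T cells, were higher in monocyte-like cells, with a median of 0.84 and 10 of 10 members above 0 (H2-Aa 1.56, H2-Ab1 1.45, H2-Eb1 1.17, Cd74 1.12).

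**Figure D3:**
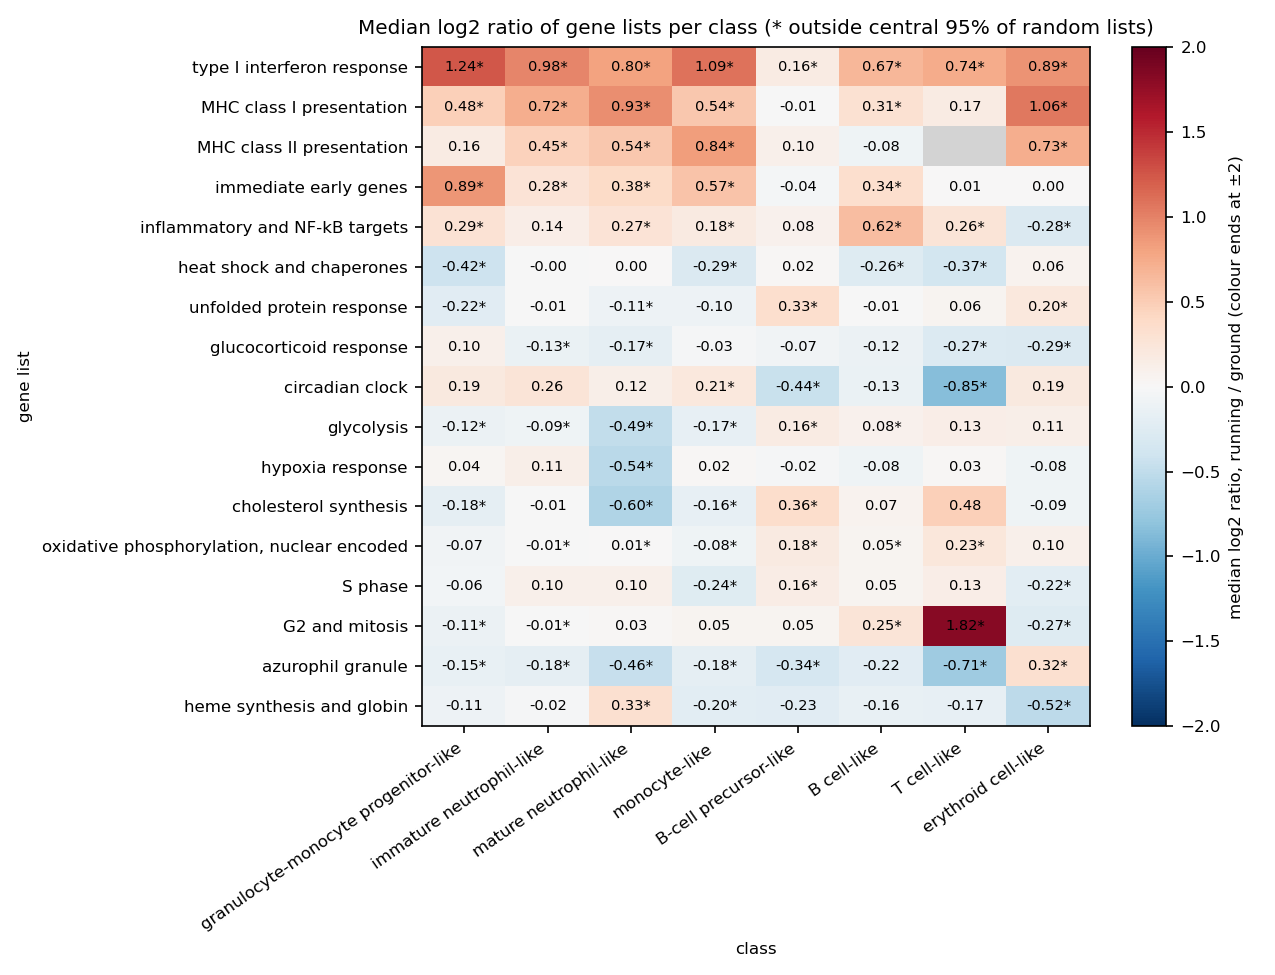
Median log2 ratio (running over ground) of 17 gene lists in 8 classes; colour and printed value give the median, and a star marks a median outside the central 95% of random lists. The type I interferon list is above 0 in all 8 classes, from 0.16 in B-cell precursor-like to 1.24 in progenitor-like cells.

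Mature neutrophil-like cells of running had lower expression of glycolysis, hypoxia and cholesterol genes. Glycolysis genes had a median of −0.49, with 15 of 16 below 0 (the glucose transporter gene Slc2a1 −1.72, the phosphofructokinase genes Pfkp −0.79 and Pfkl −0.79). Hypoxia response genes had −0.54, with 12 of 17 below 0 (P4ha1 −2.77, Ankrd37 −2.58, Pdk1 −1.99) and 4 higher by their intervals. Cholesterol synthesis genes had −0.60, with 14 of 14 below 0 (Stard4 −1.24, Idi1 −1.10). All 3 medians lay below those of all random lists. The secreted peptide gene Prok2 (−2.94), Igfbp6 (−3.27) and the semaphorin gene Sema6b (−3.41) were lowest, and beside H2-Q6 and H2-Q7 the transglutaminase gene Tgm3 was highest (2.36). Different clusters held most of this class in each library: clusters 9 and 2 held 45.5% and 20.2% of it in ground, and clusters 20 and 14 held 36.2% and 31.0% in running. In cluster 17, with 27.7% and 26.9% of the class, the medians were −0.22 for glycolysis, −0.07 for hypoxia and −0.61 for cholesterol synthesis, and single genes stood at −2.10 for Sema6b, −2.42 for Igfbp6, −1.81 for Prok2, 1.77 for Tgm3 and 3.80 for H2-Q6. The median of all genes in the class was 0.11. Relative to it, the medians were −0.60 for glycolysis, −0.65 for hypoxia, −0.71 for cholesterol synthesis, 0.69 for the interferon list and 0.82 for MHC class I presentation.

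In the earlier stages, immature neutrophil-like cells of running had less Lipg (−2.75), less of the stefin gene Cstdc5 (−1.71, or −2.63 with 1 doublet threshold for both libraries) and less of the uridine phosphorylase gene Upp1 (−1.27), and more Oasl2 (2.08). Their glucocorticoid response genes had a median of −0.13, at percentile 0.01 (the clock gene Per1 −0.65, Cdkn1a −0.44), with 8 of 12 members below 0. By their intervals 5 members were lower and 4 higher, so the list was split. Progenitor-like cells had higher immediate early genes, which respond within minutes to stimulation, with a median of 0.89 and 15 of 15 members above 0 (Egr1 1.53, Fos 1.50, Atf3 1.08). The list was also higher in immature (0.28) and mature (0.38) neutrophil-like cells, so the difference was not particular to progenitor-like cells. Whether handling of the 2 libraries sets it was not tested. Heat shock and chaperone genes were lower in progenitor-like cells, with a median of −0.42 and 11 of 11 below 0 (Hspa1b −1.69, Hspa1a −1.08, Hsph1 −0.85), as was the kinase gene Pim1 (−1.08, or −2.02 as a mean of CPM over cells). Genes of the unfolded protein response had −0.22 (the asparagine synthetase gene Asns −0.76, Ddit3 0.49), and genes of apoptosis and p53 targets 0.38 (Trp53inp1 0.76, Pmaip1 0.66).

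In monocyte-like cells Saa3 (−3.59, −4.18 to −3.06, with 161 of its 424 ground UMIs in a single cell), the NF-κB cofactor gene Bcl3 (−1.85) and the glycoprotein gene Lrg1 (−1.70) were the lowest, and Ifit3, Rcn2 and H2-Q6 (1.79) the highest. As a mean of CPM over cells, Saa3 stood at −2.67, Lrg1 at −2.74 and H2-Q6 at 0.73. Immediate early genes had a median of 0.57 (Atf3 1.20, Klf6 0.89, Fos 0.84), with Ier3 as the exception at −0.96, and heat shock genes −0.29 (Hsph1 −0.67, Hsp90aa1 −0.42). S phase genes were lower, with a median of −0.24 and 18 of 18 below 0 (Cdc6 −0.47, Tyms −0.46), while G2 and mitosis genes stood at 0.05 (percentile 89.6). The lipid handling list had a median of −0.04, although Lpl (2.37) and the fatty acid transporter gene Cd36 (1.19) were higher.

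In macrophage-like cells the nuclear envelope gene Syne1 (1.73, 0.92 to 2.67, or 0.91 as a mean of CPM over cells), Cd5l (1.53) and the haemoglobin scavenger receptor gene Cd163 (1.16) were highest in the ranking, which left out markers of other cell types such as Ccr3 (1.45, 16 and 200 UMIs). Syne1 was also a leading gene of a small immature neutrophil-like cluster found with doublets kept (14 ground and 31 running cells). The chaperone gene Hsp90b1 (−1.06), the transcription factor gene Zeb2 (−1.05) and the splicing factor gene Rbm39 (−0.84) were lowest. In this class the neutrophil gene S100a8 stood at 38270 CPM in ground and 66380 CPM in running. A larger part of neutrophil RNA lowers the CPM of other genes, and C1qb, a leading gene of the class, stood at −0.54. The ratios in this class therefore do not measure macrophage expression alone. Oxidative stress genes had a median of 0.22 (Slc7a11 1.68, Hmox1 1.13). Specific granule genes, which belong to neutrophils, had 0.94 (Lcn2 1.35, Camp 1.32). The haem and globin list stood at −4.87, but a single ground cell held 2070 of the 2174 haemoglobin UMIs of the class there.

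T cell-like cells of running carried more transcripts of dividing and of cytotoxic cells. G2 and mitosis genes had a median of 1.82, with 12 of 12 above 0 (Cenpf 2.40, Ube2c 2.29, the proliferation marker Mki67 1.94), whereas S phase genes stood at 0.13 (percentile 90.3), and the histone genes Hist1h1b (2.10) and Hist1h2ap (1.80) were among the highest. Genes of NK and T cytotoxicity had a median of 0.43 (Ifng 1.85, the granzyme genes Gzmb 1.54 and Gzma 0.99). At Leiden resolution 2 the class was divided into a cluster led in part by Ccl5 and Il2rb (69 ground and 125 running cells) and a cluster led in part by Cd8b1 and Bcl11b (137 and 163 cells), so the mix within the class also differed. Lymphoid development genes had −0.42 (Lef1 −0.77, Il7r −0.71), and the corepressor gene Nrip1 (−1.17) and the chaperone genes Hsph1 (−0.83) and Stip1 (−0.77) were lowest. These values come from 207 ground and 288 running cells, with medians of 4491 and 5762 UMIs, and 1 running cell held 66 of the 161 UMIs of Ifng. As a mean of CPM over cells, Hist1h1b stood at 1.20 and Mki67 at 1.10.

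In B-cell precursor-like cells of running the lymphoid development genes had a median of −0.31 (percentile 0.02), with 9 of 14 members below 0. The members with the largest ratios went both ways, with the early genes Dntt (0.71), Igll1 (0.66) and Vpreb1 (0.65) higher and the recombinase gene Rag1 (−0.58) lower. The signalling inhibitor gene Socs2 (1.78), Myl10 (1.50) and Egr1 (1.16) were highest, and the chemokine gene Cxcl2, also a leading gene of mature neutrophil-like clusters 2 and 9 (−1.70, or −0.81 as a mean of CPM over cells and −2.55 with 1 doublet threshold for both libraries), the glucocorticoid-induced gene Tsc22d3 (−1.15) and the phosphatase gene Ppm1e (−1.03) lowest. Cholesterol synthesis genes had a median of 0.36 (Idi1 1.32, Cyp51 1.02) and unfolded protein response genes 0.33 (Sdf2l1 0.75, Manf 0.49). Dntt, Igll1 and Vpreb1 are also leading genes of cluster 6, which held 30.3% of this class in ground and 41.3% in running, and Rag1 of cluster 8. At Leiden resolution 2 Myl10 was a leading gene of a cluster of 69 ground and 141 running cells, so its ratio can reflect this mix too. Whether the list medians of the class follow the mix was not tested.

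In B cell-like cells of running the immediate early genes were higher, with a median of 0.34 (Fos 2.31, Fosb 1.36, Dusp1 1.16), and heat shock genes lower (median −0.26, Hsph1 −1.30). Gda, which encodes guanine deaminase (1.88), and the histone gene Hist1h2ab (1.49) were also high, and Tsc22d3 (−0.84) and the chemokine receptor gene Cxcr4 (−0.83) low. Inflammatory genes had 0.62 (Ccl6 2.33, Il1b 1.95), but cluster 30, with 7 ground and 37 running cells and neutrophil transcripts, moved this value. Without that cluster the CPM ratio of Il1b was 0.757 in place of 3.85, that of the neutrophil gene S100a8 0.940 in place of 2.57, and that of Fos 3.26 in place of 4.96. The median of the inflammatory list was then −0.19 and that of immediate early genes 0.10. With doublets kept, Gda stood at −0.14 and Fos at 0.81, and Gda stood at 1.08 as a mean of CPM over cells.

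Erythroid-like cells of running had lower CPM of haem synthesis and globin genes, with a median of −0.52 and 15 of 15 members below 0 (the mitochondrial iron importer gene Slc25a37 −0.90, Hba-a1 −0.79, Alas2 −0.78). Genes of G2 and mitosis had −0.27, with 20 of 20 below 0 (Mki67 −0.48, Cenpf −0.45), and S phase genes −0.22 (Rrm2 −0.46, Pcna −0.46). The interferon-induced gene Rtp4 (1.89) was higher, and the death receptor gene Tnfrsf21 (−1.75, or −2.51 as a mean of CPM over cells), Lrg1 (−1.53) and the protease gene Adam33 (−1.30) lower. The class had medians of 8245 UMIs in ground and 15921 in running. Over all classes and all cells, 137 of 275 list medians lay outside the central 95% of random lists, which hold unrelated genes, so the count gives no error rate for a difference between the groups.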

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

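The tests of the macrophage-like share and of Rcn2, the test of neutrophil RNA without cluster 30 and the tests of single classes for a shift between clusters were chosen only after the result was seen.

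Some gene lists stood outside the central 95% of random lists in opposite directions in different classes, and none of these differences between classes was tested. For 5 of the 11 lists an alternative turned a direction or left it close to 0, and its value is given beside them. The difference of the median log2 ratios was 2.08 for G2 and mitosis genes (T cell-like 1.82, erythroid-like −0.27), 1.07 for the circadian clock (monocyte-like 0.21, or −0.11 over members with at least 200 UMIs, T cell-like −0.85 from 3 genes) and 1.03 for azurophil granule genes (erythroid-like 0.32, or −0.15 with doublets kept, T cell-like −0.71). It was 0.96 for specific and gelatinase granule genes (T cell-like 0.59, or −0.43 with doublets kept, erythroid-like −0.37), 0.953 for cholesterol synthesis (B-cell precursor-like 0.36, mature neutrophil-like −0.60) and 0.906 for inflammatory genes (B cell-like 0.62, or −0.19 without cluster 30, 0.03 with doublets kept and −0.035 over members with at least 200 UMIs, erythroid-like −0.28). It was 0.848 for leukocyte homing and release (B cell-like 0.45, or 0.01 without cluster 30 and 0.05 with doublets kept, erythroid-like −0.40), 0.842 for haem and globin synthesis (mature neutrophil-like 0.33, or 0.15 in cluster 17, erythroid-like −0.52) and 0.650 for glycolysis (B-cell precursor-like 0.16, mature neutrophil-like −0.49, or −0.22 in cluster 17). For apoptosis and p53 targets it was 0.642 (progenitor-like 0.38, or 0.23 over members with at least 200 UMIs, erythroid-like −0.26), and for the unfolded protein response 0.553 (B-cell precursor-like 0.33, progenitor-like −0.22). Granule genes in T cell-like and erythroid-like cells, and globin genes in mature neutrophil-like cells, can be free RNA. The granule gene Camp, at a log2 ratio of 0.59, was seen in 76.3% of ground and 74.3% of running T cell-like cells.

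Macrophage-like cells made up a larger share of the running library. Their barcodes also held much neutrophil RNA, with S100a8 at 38270 CPM in ground and 66380 CPM in running. In mature neutrophil-like cells S100a8 stood at 144200 and 140200 CPM. Whether each of these shallow barcodes counts 1 whole macrophage was not tested. The UMI minimum cannot be told apart from a larger share, since it could remove more of the shallower ground cells and raise the ratio, which was 4.21 (23 and 102 cells) at 1000 UMIs, inside the interval of 2.52 to 4.40 at 500. Fewer cells of other classes in the denominator would raise rare classes alike, but the ratio for basophil or mast cell-like cells was 0.9999 (0.767 to 1.30). A higher yield of adherent cells from the running marrow may account for the share, since stromal-like cells were also more frequent, at a ratio of 2.07 (1.27 to 3.40). Running itself stays open, as does another difference between the mice of the 2 libraries, and neither was tested.

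Rcn2 was higher in running in the 8 classes other than macrophage-like cells. Free RNA would add a like amount to each class, but the excess in progenitor-like cells was 13.7 CPM and in immature neutrophil-like cells 1.75 CPM, 7.8 times as much. A different mix of classes is argued against by the 3.74-fold ratio over all cells with the class proportions of ground. That value does not account for a different mix of cells inside a class, which stays open. In mature neutrophil-like cells the log2 ratio was 1.73, or 0.69 in cluster 17 alone. A difference between the mice other than running could shift the gene in every class, and with a lowest ratio of 2.27-fold over the classes it cannot be told apart from running, because each group has 1 library. Gm47283 (log2 2.92 to 4.25), Slc15a2 (1.38 to 2.23) and H2-Q7 (0.17 to 5.07), chosen after their values were seen, were also higher in all 8 classes, so a variant between the mice stays open, as does running, which was not tested.

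Type I interferon genes had a median above 0 in the 8 classes, though only 0.16 in B-cell precursor-like cells, where 2 of 11 members were higher and 2 lower by their intervals. Neutrophil RNA free in the droplets could give 38.3% of the excess of the median member in B cell-like cells, which decides neither way, but at most 6.56% in T, B and erythroid-like cells without cluster 30, which argues against it there. A shift between clusters is argued against in the monocyte-like clusters tested (lowest median 0.58, with a median lower bound of its members of 0.29). Progenitor-like cells (median 1.24, lower bound 0.56) and T cell-like cells (0.74, −0.01) are each 1 cluster. Their cluster median is the class median, so it cannot decide on a shift between finer groups of cells. At Leiden resolution 2 progenitor-like cells were divided into a cluster of 277 ground and 173 running cells and a cluster of 97 and 66. Within erythroid-like cluster 5 the median was 0.9639 (lower bound 0.7221), which argues against a shift between the clusters of resolution 1 there. Such a median cannot decide on a shift between finer groups inside a cluster, in this or the other classes. At Leiden resolution 2 erythroid-like cells included a cluster of 207 ground and 133 running cells and a cluster of 75 and 118. Erythroid-like cluster 21 was not among the clusters measured. Immature neutrophil-like clusters 0 (1.0045, 0.6301) and 4 (0.5716, 0.1498) argue against a shift between clusters too, but cluster 13 (0.4682, −0.0387) decides neither way. In mature neutrophil-like, B-cell precursor-like and B cell-like cells such a shift cannot be told apart from a response within clusters. Of the 19 clusters with at least 100 cells in each library and 3 measured members, 18 had a median above 0 (0.0078 in B-cell precursor-like cluster 6). The 19 leave out the large mature neutrophil-like clusters 9 and 14. Mature neutrophil-like cluster 20, which is led in part by the list members Oasl2 and Rtp4, had −0.88. A difference between the mice other than running cannot be told apart from running, because each group has 1 library. Both stay open and were not tested.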

How the results depend on the processing

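Chosen only after the data had been seen were the tests of list medians with the class proportions of ground, with 1 doublet threshold for both libraries, without B cell-like cluster 30 and with mature neutrophil-like cluster 17 alone. No paired analysis was possible because each group has 1 library. Of the alternative values for ratios of shares, 104 of 105 lay inside the interval of the reported value, some of them across 1 where that interval included 1, and so did 454 of 509 for single genes, while 794 of 879 list medians lay between the medians of the members' lower and upper bounds without a called direction turning. The exception among shares was the immature neutrophil-like ratio of 0.926 at Leiden resolution 2. Centring on the median of all genes gave MHC class I presentation 0.53 in all cells and 0.82 in mature neutrophil-like cells, and turned oxidative phosphorylation in mature neutrophil-like cells to −0.10. Members with at least 200 UMIs gave an interferon median of 0.49 in progenitor-like cells, and in monocyte-like cells −0.0026 for inflammatory and −0.11 for circadian genes. In B cell-like cells the inflammatory median turned to −0.19 without cluster 30 and −0.035 over members with at least 200 UMIs. Glycolysis there turned to −0.28 with doublets kept and −0.013 without cluster 30, specific granule genes to −0.79 and −0.14, and secreted factors to −0.17 without cluster 30. Doublets kept also turned Gda in B cell-like cells (−0.14), specific granule genes (−0.43) and secreted factors (−0.19) in T cell-like cells, and azurophil genes in erythroid-like cells (−0.15). In cluster 17 the glucocorticoid list had 0.0062 and the unfolded protein response 0.070. The share of monocyte-like cells with an Rcn2 UMI was higher in running by 1.19 percentage points after thinning. For all of these the cause was not tested. Class proportions of ground moved 11 of 23 gene values over all cells and 17 of 31 list medians, among them niche factors (−0.162), lymphoid development (−0.0921) and lipid handling (0.0139), which turned, and MHC class I presentation (0.566). A mean of CPM over cells moved 23 of 72 gene values, and cluster 17 alone 7 of 8. Depth limits macrophage-like cells most, with 1 and 4 Rcn2 UMIs.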

Other observations

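The values at the class proportions of ground and of the STAT3 list in cluster 17 were chosen after the results had been seen, and the list of STAT3 pathway genes and targets was written after the lower acute-phase genes had been noticed, and the values of its member Cebpd had been seen.

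Beyond the lists described for single classes, genes of NK and T cytotoxicity had a median log2 ratio of 0.98 over all cells, with 12 of 13 members above 0 (Ifng 2.24, Xcl1 1.27, Gzmk 1.20), but of 0.26 with the class proportions of ground. Lymphoid development genes had 0.29 over all cells, with 14 of 15 above 0 (Igll1 1.45, Vpreb1 1.42, Dntt 0.96), but −0.09 with the class proportions of ground and −0.31 in B-cell precursor-like cells. The circadian clock had 0.25 over all cells, with 12 of 14 above 0 (Nr1d1 1.03, Ciart 0.93), but 0.11 with the class proportions of ground, −0.44 in B-cell precursor-like cells and −0.85 in T cell-like cells. Oxidative phosphorylation genes, which supply the respiratory chain, had 0.23 in T cell-like cells (35 of 39 above 0, Sdhc −0.53, Ndufv3 0.42) and 0.18 in B-cell precursor-like cells (36 of 39 above 0, Atp5g1 0.50, Atp5k 0.45). Genes of leukocyte retention, homing and release had −0.33 in B-cell precursor-like cells, with 13 of 13 below 0 (Cxcr4 −0.94, Cxcr2 −0.49). Cxcr2 is a mature neutrophil marker and can be free RNA there, and the neutrophil gene S100a9 stood at −0.25 in the same cells. The mix of clusters also differed, with cluster 6 at 30.3% of the class in ground and 41.3% in running.

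The acute-phase genes Saa3 and Lrg1 were lower in running monocyte-like cells. A candidate explanation is weaker STAT3 signalling in running than in ground. A separate list of 9 STAT3 pathway genes and targets had a median of −0.31 in mature neutrophil-like cells (percentile 0.01, 5 of 8 measured members below 0), −0.40 in their cluster 17 (6 of 8) and −0.34 in monocyte-like cells (percentile 0.02, 6 of 8), with Socs3, a feedback inhibitor of the pathway, at −1.29 in the latter. Progenitor-like cells had −0.27 (percentile 0.12) and immature neutrophil-like cells −0.15 (percentile 0.24). In B-cell precursor-like (−0.37, percentile 3.80), T cell-like (−0.27, percentile 4.64), B cell-like and erythroid-like cells the median was also below 0 but inside the central 95%, so the data do not show it to be limited to myeloid cells. The direction is as the hypothesis needs, but with 1 library per group it remains a hypothesis.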
